A study of Mus musculus with 36 samples.

How the data were processed

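Total RNA from minced and homogenized colons was extracted with TRIzol, labelled with biotin and hybridized to Affymetrix HT MG-430 PM arrays, 1 array per sample. The values were deposited by the authors as intensity per probe set on a linear scale, rounded to whole numbers, and the background correction, normalization and summarization are not given in the sources used here. The table had 45037 probe sets and 36 arrays, with values from 4 to 14185. Correlations between arrays on the log2 scale lay between 0.913 and 0.995, and 0 pairs of arrays were identical. An array has no read depth, and its precision is limited by the number of arrays and by signals near background. The labels give genotype, stage and replicate number, but no batch or date of hybridization. Each array was taken as 1 animal, and p-values measure the spread between these samples.

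Intensities were put on the log2 scale after adding 1 and quantile normalized, since the medians of the arrays differed. Of the probe sets, 28898 had exactly 1 gene symbol, 551 had several and 15588 had none in the table used here, and only the first kind was kept. Each gene was represented by the probe set with the highest mean over all arrays, which left 17097 genes. Probe sets of gene families with near-identical members can bind more than 1 member. Comparisons were tested with limma 3.58.1 in R 4.3.3, as a model with 1 mean for each of the 8 groups over all 36 arrays and moderated variances with an intensity trend. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The 15 comparisons were each stage against untreated within a genotype, KO against WT at each stage, the interactions of genotype and stage, and day 15 against day 7 and tumor against day 15 over the mean of both genotypes. A set of 35 gene lists with 548 symbols, of which 473 were measured, was tested with camera of limma at a preset correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry were alternatives. Counts over the list alone were adjusted over its members only, and the lists described were chosen after their values were seen. Some genes belong to more than 1 list, such as Lgr5, Axin2 and Ascl2 to stem cell genes and Wnt targets, and Saa3 to IL-17-induced and acute-phase genes.

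Groups, comparisons, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule took, per comparison, the 8 largest rises and the 8 largest falls among genes past the threshold whose groups of arrays did not overlap, up to 4 members with the smallest p of each list described, Il17rc, and members of the lists on IL-17 signalling. For interactions and means over genotypes, overlap was not considered. Genes named by the rule whose call was lost without a single array were mostly left out of the text after their values were seen, and not all members on IL-17 signalling are printed. Clca3b was named after its values were seen, as the remaining call between tumors. Alternatives were a pseudocount of 16, centring in place of quantile normalization, leaving out the dimmest genes, the mean of all probe sets or every probe set tested, other variance moderation, array weights, only the groups compared, the letter or number of the title code or the replicate number as a block, and leaving out each array in turn. Chosen after seeing the data were no quantile normalization, leaving out the 2 arrays labelled KO day 7 with high Il17rc, the 7 arrays with Krt5 above 100, the array with Y-linked transcripts or replicate 4 of both genotypes at day 15, and the level of the squamous list as a covariate. The quantile normalization listed as an alternative was the setting used.

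Whether equal replicate numbers pair samples was checked by correlating residuals. Every pair had a correlation above 0.1 for WT day 7 and untreated (0.165 to 0.397) and for KO and WT at day 15 (0.173 to 0.8), and for no other comparison. The labels do not state a pairing, so samples were treated as unpaired and the blocked counts are given beside these comparisons. The procedure was tested on simulated data with 100 changed genes of each size among 17097 genes. It recovered 54 to 89% of changes of 1 log2 unit and 88 to 97% of changes of 2 log2 units over the 15 comparisons, and 2.66 to 8% of the calls were false. Camera called 15 of 15 shifted lists and 3 of 480 others. Chromosomes came from the GRCm38.p6 annotation, to which 28689 probe sets were matched by gene identifier. For each count of genes, splits of the same arrays into groups of the same sizes were also run, with 100 drawn where there were more.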

Results

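The series measured gene expression in the colon of wild-type mice (WT) and of mice without a working Il17rc gene (KO), which encodes a receptor subunit for the cytokines IL-17A and IL-17F. Mice 6 to 8 weeks old received azoxymethane, a carcinogen that acts on the colon, and then 3 cycles of 3% dextran sulfate sodium in the drinking water, which injures the colon lining. Each cycle had 5 days of dextran sulfate sodium and 14 days of plain water. Per the labels, each genotype had 4 untreated arrays, 4 at day 7, 4 at day 15 and 6 tumor arrays at day 63, so 36 arrays in 8 groups. On each array the median deposited intensity lay between 14 and 16, and 36% of the 17097 genes tested had a mean below 16. Log2 differences are given with the standard error of the limma model, and list sizes count measured genes. For the genes named as the largest changes between 2 groups, all arrays of a group lay above all arrays of the other. For 91 of 231 named values, a group compared had a mean intensity below 16, near background, and the size of the log2 difference then depends on the pseudocount.

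Il17rc served as a check of the genotype labels. Its brighter probe set averaged 291.8 ± 38.7 (SD, n = 4) in untreated WT, 413.2 ± 76.3 (n = 4) at day 7, 252 ± 101 (n = 4) at day 15 and 119.7 ± 52.4 (n = 6) in tumors, with single WT arrays between 76 and 515. In KO arrays other than those labelled day 7 it lay between 7 and 15. A second probe set stayed near the lowest intensities in both genotypes. The array labelled KO day 7 replicate 1 had an Il17rc intensity of 331, inside the WT range, and replicate 2 had 44. Replicates 3 and 4 of that group had values like the other KO arrays. Il17rc was lower in KO than in WT by limma at each stage, by a log2 difference of -4.72 ± 0.57 untreated, -3.41 ± 0.57 at day 7, -4.31 ± 0.57 at day 15 and -3.51 ± 0.47 in tumors, with adjusted p = 1.52e-06, 0.00355, 0.000247 and 0.000135. Low KO levels lie near background, so these sizes depend on the pseudocount and were -3.53, -2.76, -3.21 and -2.36 with a pseudocount of 16. Arrays labelled KO day 7 also had more Il17rc than untreated KO arrays (1.83 ± 0.57, adjusted p = 0.0314). That call ended without KO untreated replicate 1 (adjusted p = 0.0897), 3 (0.0621) or 4 (0.0689) and without KO day 7 replicate 1 (0.191) or 2 (0.0847). Without replicates 1 and 2 the KO to WT difference at day 7 was -5.13. Because the label of replicate 1 is in doubt, day 7 results for KO are stated for arrays labelled KO day 7.

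**Figure D1:**
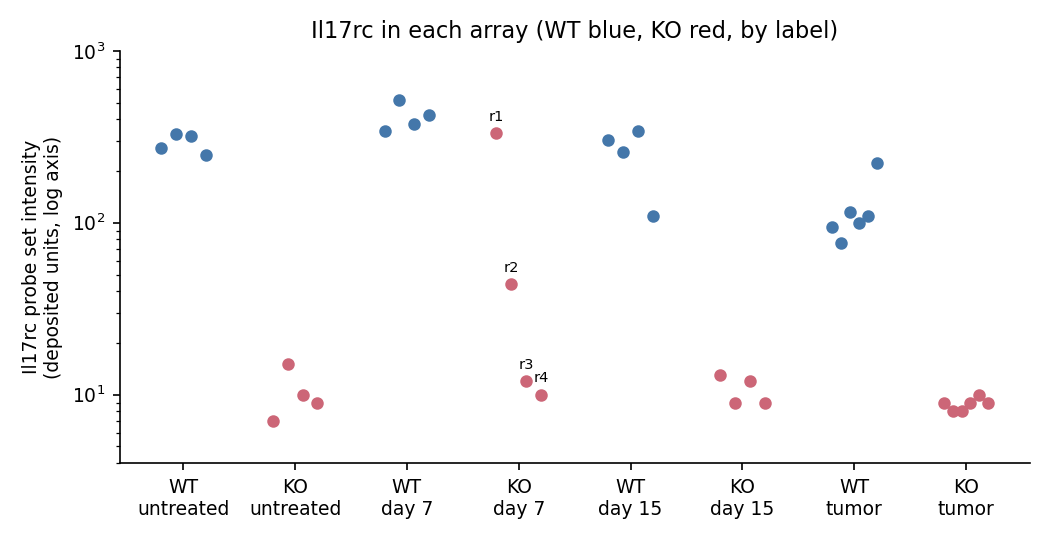
Deposited Il17rc intensity (log axis) of each of the 36 arrays, in the 8 groups by genotype and stage, as 1 point per array with WT in blue and KO in red. WT arrays lie between 76 and 515 and KO arrays between 7 and 15, except the arrays labelled KO day 7 replicate 1 at 331 and replicate 2 at 44.

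Some arrays carried tissue that their group as a whole did not. Krt5, a keratin of stratified squamous epithelium, had an intensity above 100 in 7 arrays. These were WT untreated replicates 1 (6043) and 4 (2199), WT day 7 replicates 1 (817) and 4 (205), KO day 7 replicates 1 (4230) and 2 (1006) and KO tumor replicate 2 (436). KO tumor replicate 1 had Krt5 at 96, below that limit, and Krt14, another squamous keratin, at 453. The 2 untreated WT arrays in this set have no counterpart among untreated KO arrays. At day 15, replicate 4 of both genotypes had the highest S100a8 intensities of the series, 5585 in WT and 6239 in KO. S100a8 encodes a protein abundant in neutrophils. In untreated and day 7 arrays it was 35 to 1980 with Krt5 above 100 and 7 to 14 otherwise. KO tumor replicate 4 had an intensity of 139 for the Y-linked gene Eif2s3y, where the other arrays had 7 to 11, and of 39 for Xist, the RNA of the inactive X chromosome, where the others had 1283 to 2735. WT tumor replicate 6 had fewer Wnt target transcripts and more smooth muscle transcripts than the other WT tumors. Comparisons that involve them were also run without the array sets listed with the alternatives and without each array in turn.

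Untreated KO and WT colons were compared to see what the genotype changed before the protocol. Untreated KO colons had more transcripts of interferon-stimulated genes than untreated WT colons. The tryptophan-degrading enzyme Ido1 differed by 6.82 ± 0.78 log2 units and the ubiquitin-like modifier Ubd by 6.42 ± 0.62. The interferon-inducible GTPases Tgtp1 (5.67 ± 0.67), Iigp1 (5.27 ± 0.66) and Ifi47 (4.77 ± 0.50) were higher as well, as were the T cell chemokine Cxcl9 (5.03 ± 0.88) and Il18bp (4.41 ± 0.37), which binds interleukin-18. These 7 genes had adjusted p = 0.000397 or lower. Of the 17 genes of interferon-gamma and antigen presentation, 17 were higher (17 over the list alone), with a median log2 difference of 3.03 (camera adjusted p = 1.71e-47, 0.00277 with an estimated correlation). They include the immunoproteasome subunits Psmb8 (3.03 ± 0.35) and Psmb9 (3.41 ± 0.42) and the class II loading factor H2-DMb1 (3.42 ± 0.42). Among 14 type I interferon-stimulated genes the median log2 difference was 2.54, and 13 were higher (13 over the list alone, camera adjusted p = 1.13e-25, 0.0188 with an estimated correlation). Members were Ifit2 (4.10 ± 0.58), Zbp1 (3.10 ± 0.47) and Cmpk2 (2.46 ± 0.39). The T cell markers had a median log2 difference of 0.67 over 16 members, of which 7 were higher (9 over the list alone, camera adjusted p = 1.4e-12, 0.0188 with an estimated correlation). The granule proteases Gzma (3.45 ± 0.31) and Gzmb (2.83 ± 0.33) and the T cell receptor chain Cd3d (2.07 ± 0.41) were higher. Among 16 monocyte and macrophage markers the median log2 difference was 1.01, and 1 was higher (9 over the list alone, camera adjusted p = 5.62e-07, 0.398 with an estimated correlation). Of the 8 plasma cell markers, 4 were higher (7 over the list alone), with a median log2 difference of 1.21 (camera adjusted p = 8.23e-08, 0.0188 with an estimated correlation). The IgM heavy chain Ighm differed by 3.57 ± 0.77, and the monocyte chemokine Ccl7 was the member of the IL-17-induced list that passed (2.65 ± 0.42).

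Lower in untreated KO than WT, besides Il17rc, were the cytochrome P450 gene Cyp2c55 (-4.39 ± 0.91), Erdr1 (-3.24 ± 0.56), the glutathione transferase Gsta4 (-2.60 ± 0.51) and Il17re (-1.03 ± 0.23), an IL-17C receptor subunit. Reasons were not tested. The smooth muscle genes had a median log2 difference of -0.39 over 14 members, of which none passed over all genes (none over the list alone, camera adjusted p = 0.0199, 0.887 with an estimated correlation). That list passed no longer without WT untreated replicate 2 (camera adjusted p = 0.0676). Among 13 squamous epithelium markers the median log2 difference was -3.14, and none passed over all genes (none over the list alone, camera adjusted p = 3.11e-07, 0.398 with an estimated correlation, median -1.59 without WT untreated replicate 1). In all, 388 genes differed, 305 higher and 83 lower in KO. Without the 7 arrays with Krt5 above 100 the count was 256, and the squamous list then had the opposite sign. The log2 difference of the interferon-gamma list was 3.11 in that setting.

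**Figure D2:**
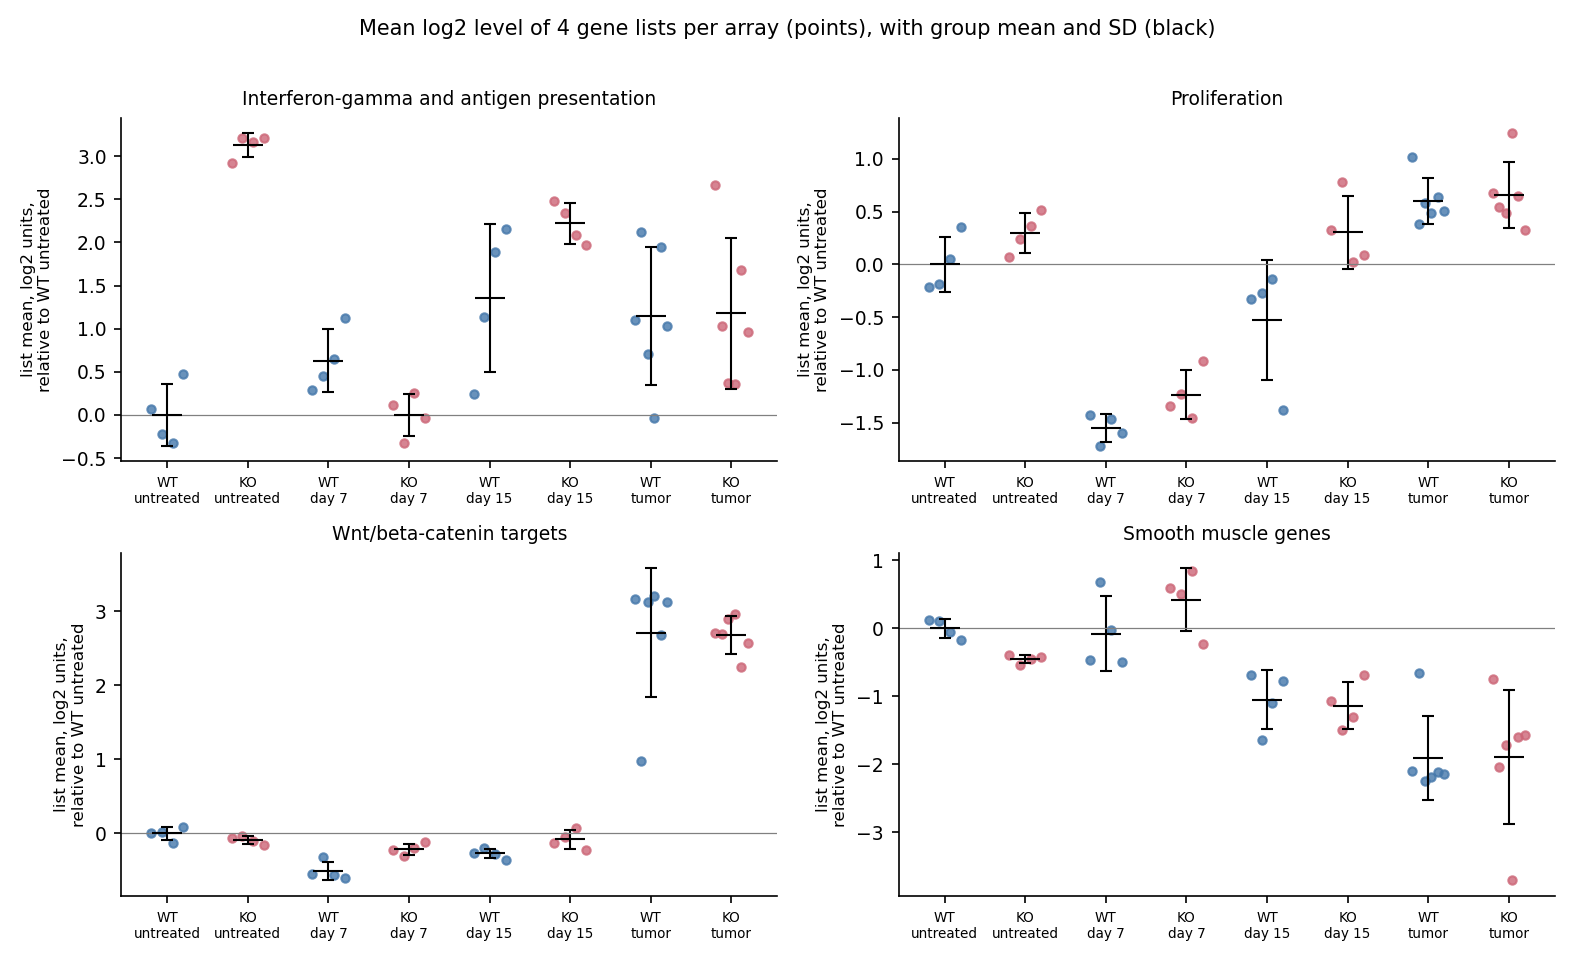
Mean log2 level of 4 gene lists in each array (points), relative to the mean of untreated WT, with group mean and SD in black, for WT in blue and KO in red at 4 stages. The interferon-gamma list is highest in untreated KO, proliferation genes are lowest at day 7 in both genotypes, and Wnt targets are high in tumors except WT tumor replicate 6.

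The first weeks of the protocol in WT colon were described by day 7 and day 15 arrays against untreated arrays. At day 7, genes of cell division fell. The mitotic kinase genes Pbk and Aurkb changed by -3.06 ± 0.37 and -2.38 ± 0.30, the DNA topoisomerase Top2a by -2.52 ± 0.29, the replicative helicase subunits Mcm4 and Mcm6 by -2.11 ± 0.24 and -1.83 ± 0.21, and Uhrf1, which maintains DNA methylation, by -2.67 ± 0.31, all at adjusted p = 8.11e-06 or lower. Of the 20 proliferation genes, 17 fell (19 over the list alone), with a median log2 difference of -1.69 (camera adjusted p = 2.51e-47, 0.00338 with an estimated correlation). Ascl2, a transcription factor of intestinal stem cells, fell as well (-2.52 ± 0.43, adjusted p = 0.00039). The intestinal stem cell genes had a median log2 difference of -0.69 over 13 members, of which 1 fell (2 over the list alone, camera adjusted p = 0.000799, 0.294 with an estimated correlation, median -0.24 without WT untreated replicate 1). The goblet cell product Retnlb rose by 3.50 ± 0.74 (adjusted p = 0.00601), the protease inhibitor Slpi by 2.01 ± 0.33 and serum albumin, Alb, by 1.98 ± 0.40. In all, 52 genes rose and 231 fell, a share of rises of 18.4% that was 8.59% with each array centred on its median and 12.8% without quantile normalization. The count of 283 was 188 without WT untreated replicate 1, and 66 without the 7 arrays with Krt5 above 100. With the replicate numbers as a block, the count was 268.

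Among the largest rises in WT at day 15 were an acute-phase gene, chemokines and a matrix-degrading enzyme. Retnlb rose by 6.90 ± 0.74, the acute-phase gene Saa3 by 6.27 ± 0.89, the protease inhibitor Serpina3n by 5.11 ± 0.75, the B cell chemokine Cxcl13 by 4.77 ± 0.91, the stromelysin Mmp10 by 4.10 ± 0.80 and the monocyte chemokine Ccl8 by 3.64 ± 0.79, with adjusted p = 0.00807 or lower. The largest falls included Pcp4 (-3.05 ± 0.59), Dpyd (-2.50 ± 0.22), Itih2 (-2.22 ± 0.28) and Ckm (-2.11 ± 0.39), of which Dpyd breaks down pyrimidines and Ckm is the muscle creatine kinase. Of the 15 antimicrobial and acute-phase genes, 4 rose (4 over the list alone), with a median log2 difference of 0.59 (camera adjusted p = 9.72e-08, 0.0307 with an estimated correlation). Slpi and Ido1 were among them (2.71 ± 0.33 and 3.96 ± 0.78), and Ido1 overlapped between the groups. The monocyte and macrophage markers had a median log2 difference of 1.53 over 16 members, of which 8 rose (15 over the list alone, camera adjusted p = 3.12e-14, 0.115 with an estimated correlation). The macrophage lysozyme Lyz2 rose by 1.87 ± 0.29. Among 11 B cell markers the median log2 difference was 1.12, and 5 rose (10 over the list alone, camera adjusted p = 9.3e-10, 0.157 with an estimated correlation). The B cell receptor component Cd79b rose by 3.16 ± 0.63 and the B cell scaffold protein Bank1 by 3.07 ± 0.69. Of the 16 T cell markers, 5 rose (10 over the list alone), with a median log2 difference of 0.57 (camera adjusted p = 3.59e-08, 0.115 with an estimated correlation). Cd3d rose by 1.92 ± 0.41.

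The IL-17-induced genes had a median log2 difference of 1.10 over 28 members, of which 5 rose (14 over the list alone, camera adjusted p = 4.58e-11, 0.115 with an estimated correlation, median 0.69 without WT day 15 replicate 4). Saa3 and the collagenase Mmp13 (3.64 ± 0.72) belong to this list. Among 16 matrix metalloproteinases and their inhibitors the median log2 difference was 0.96, and 5 rose (8 over the list alone, camera adjusted p = 1.14e-08, 0.157 with an estimated correlation, median 0.42 without WT day 15 replicate 4). Of the 14 genes of the IL-6 family and STAT3, 3 rose (5 over the list alone), with a median log2 difference of 0.56 (camera adjusted p = 1.4e-07, 0.157 with an estimated correlation, median 0.19 without WT day 15 replicate 4). Among them, Lrg1 (3.57 ± 0.51) and Socs3 (3.40 ± 0.49) rose, of which Socs3 is a feedback inhibitor of cytokine signalling. In WT at day 15, 358 genes rose and 219 fell. The count of 577 was 311 without WT day 15 replicate 1 and 378 without WT day 15 replicate 2, and 266 without the 7 arrays with Krt5 above 100. It was 47 with the letter of the title code as a block, 145 with only the groups compared and 942 with array weights.

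WT tumors (day 63) were compared with untreated WT colon (day 0). In both genotypes, age, sampling time and tissue make-up thus cannot be told apart from the protocol. Matrilysin, Mmp7, a target of Wnt signalling, rose by 8.16 ± 0.41, the intestinal lectin Itln1 by 7.24 ± 0.46, and Saa3 and Retnlb by 6.53 ± 0.81 and 6.12 ± 0.68. The lipase-related genes Pnliprp1 (6.31 ± 0.49) and Pnliprp2 (5.82 ± 0.33), the Paneth cell defensin Defa21 (6.08 ± 0.80) and the antibacterial lectin Reg3b (5.89 ± 0.91) also rose. The intestinal chloride exchanger Slc26a3 (-4.34 ± 0.67), the carbonic anhydrase Car4 (-3.67 ± 0.68), the clock-controlled transcription factor Dbp (-4.04 ± 0.36) and Pcp4 (-4.09 ± 0.54) fell. These 12 genes had adjusted p = 0.000174 or lower. Of the 20 Wnt/beta-catenin targets, 18 rose (18 over the list alone), with a median log2 difference of 2.36 (camera adjusted p = 1.74e-20, 0.0203 with an estimated correlation). The secreted Wnt inhibitor Wif1 (5.70 ± 0.43) and the transcription factors Prox1 (4.09 ± 0.37) and Sp5 (3.29 ± 0.31) were among them. Among 13 intestinal stem cell genes the median log2 difference was 1.26, and 9 rose (9 rose and 1 fell over the list alone, camera adjusted p = 3.8e-05, 0.0942 with an estimated correlation). Lgr5 (3.65 ± 0.40) and Axin2 (3.05 ± 0.40), of both lists, rose. The mast cell markers had a median log2 difference of 1.20 over 11 members, of which 8 rose (8 over the list alone, camera adjusted p = 6.68e-07, 0.0821 with an estimated correlation). The mast cell proteases Mcpt2 (5.74 ± 0.36), Mcpt1 (4.42 ± 0.47) and Cpa3 (3.34 ± 0.41) rose. Of the 14 smooth muscle genes, 14 fell (14 over the list alone), with a median log2 difference of -1.83 (camera adjusted p = 5e-11, 0.241 with an estimated correlation). They include Myh11 (-2.54 ± 0.43) and Synm (-2.68 ± 0.43).

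Among 15 antimicrobial and acute-phase genes the median log2 difference was 2.23, and 9 rose (10 over the list alone, camera adjusted p = 5.23e-08, 0.0198 with an estimated correlation). Another lectin of the Reg3 family, Reg3g, rose by 4.98 ± 0.51. Of the 28 IL-17-induced genes, 14 rose (16 over the list alone), with a median log2 difference of 1.19 (camera adjusted p = 1.77e-06, 0.242 with an estimated correlation). Duoxa2, the maturation factor of a hydrogen peroxide-producing oxidase, rose by 1.06 ± 0.16. The matrix metalloproteinases and their inhibitors had a median log2 difference of 1.52 over 16 members, of which 9 rose (11 over the list alone, camera adjusted p = 4.53e-06, 0.279 with an estimated correlation). Besides Mmp7, Mmp10 (5.37 ± 0.73) and Mmp12 (3.49 ± 0.54) rose. Of the 22 absorptive colonocyte genes, 2 rose and 12 fell (2 rose and 13 fell over the list alone), with a median log2 difference of -0.99 (camera adjusted p = 1.86e-06, 0.279 with an estimated correlation). The transporter Slc37a2 (-3.58 ± 0.44) fell, while the peptide hormone uroguanylin, Guca2b, rose (2.31 ± 0.35). Among 16 monocyte and macrophage markers the median log2 difference was 1.51, and 11 rose (12 over the list alone, camera adjusted p = 2.14e-06, 0.279 with an estimated correlation). Lyz2 and the complement component C1qa rose (2.86 ± 0.27 and 1.98 ± 0.42). Il17re fell by 1.43 and the cytokine subunit Il23a rose by 1.05 ± 0.18 (adjusted p = 8.25e-06 and 6.99e-05). In all, 2144 genes rose and 1734 fell between untreated WT colon and WT tumors.

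The same stages were compared within KO. At day 7 the interferon-stimulated genes that were high in untreated KO colon were lower in arrays labelled KO day 7. Ido1 changed by -5.96 ± 0.78, Tgtp1 by -5.92 ± 0.67, Ubd by -5.88 ± 0.62, Cxcl9 by -5.17 ± 0.88, Ifi47 by -5.05 ± 0.50 and Iigp1 by -5.01 ± 0.66, with adjusted p = 0.000122 or lower. Higher were Cyp2c55 (4.10 ± 0.91), the membrane protein Mal (3.92 ± 0.81) and Alb (2.92 ± 0.40). Among 17 genes of interferon-gamma and antigen presentation the median log2 difference was -2.98, and 17 fell (17 over the list alone, camera adjusted p = 1.35e-28, 0.0236 with an estimated correlation). The invariant chain of class II molecules, Cd74 (-3.91 ± 0.47), its transcriptional activator Ciita (-2.20 ± 0.29) and Psmb8 (-2.82 ± 0.35) fell. The type I interferon-stimulated genes had a median log2 difference of -2.25 over 14 members, of which 12 fell (13 over the list alone, camera adjusted p = 1.03e-13, 0.101 with an estimated correlation). Ifit2 and the RNA-sensing enzyme Oas2 fell (-3.98 ± 0.58 and -2.08 ± 0.35). Of the 20 proliferation genes, 18 fell (19 over the list alone), with a median log2 difference of -1.56 (camera adjusted p = 5.09e-27, 0.0236 with an estimated correlation). Members with the smallest p were Aurkb (-2.85 ± 0.30), Top2a (-2.36 ± 0.29) and Cdk1 (-2.02 ± 0.26). The smooth muscle genes had a median log2 difference of 0.82 over 14 members, of which 3 rose (4 over the list alone, camera adjusted p = 0.000658, 0.741 with an estimated correlation). Of the 13 enteric neuron and glia genes, 4 rose (4 over the list alone), with a median log2 difference of 0.58 (camera adjusted p = 0.00238, 0.727 with an estimated correlation). Among 8 plasma cell markers the median log2 difference was -1.68, and 7 fell (7 over the list alone, camera adjusted p = 9.7e-08, 0.0236 with an estimated correlation). The joining chain of secreted antibodies, Jchain (-3.40 ± 0.57), and Ighm (-4.18 ± 0.77) fell.

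Of the 16 T cell markers, 7 fell (11 over the list alone), with a median log2 difference of -0.60 (camera adjusted p = 5.24e-09, 0.0792 with an estimated correlation). Gzma and Gzmb fell (-3.47 ± 0.31 and -2.70 ± 0.33). The monocyte and macrophage markers had a median log2 difference of -1.49 over 16 members, of which 10 fell (13 over the list alone, camera adjusted p = 2.55e-11, 0.161 with an estimated correlation). Lyz2, the chemokine receptor Cx3cr1 and Ccl7 fell (-1.88 ± 0.29, -1.91 ± 0.30 and -2.79 ± 0.42). At day 7, 964 genes rose and 1120 fell in KO, a share of rises of 46.3% that was 24.3% with each array centred on its median and 33.4% without quantile normalization. The count of 2084 was 1315 without KO day 7 replicate 3, and 1528 without the 2 arrays with high Il17rc.

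Among the largest rises in KO at day 15 against untreated KO were neutrophil and inflammatory genes. The calprotectin subunits S100a8 and S100a9 rose by 7.39 ± 1.32 and 6.90 ± 1.26, Saa3 by 6.08 ± 0.89, the itaconate-producing enzyme Acod1 by 5.60 ± 0.79, the neutrophil chemokine Cxcl2 by 5.55 ± 0.91 and interleukin-1 beta, Il1b, by 5.12 ± 0.85, with adjusted p = 0.00342 or lower. S100a8 averaged 9.5 in untreated KO, near background, and its rise was 6.11 with a pseudocount of 16. The calcium transport genes S100g (-3.40 ± 0.62) and Trpv6 (-2.90 ± 0.43) and Dbp (-2.23 ± 0.39) fell. Of the 17 neutrophil markers, 7 rose (12 over the list alone), with a median log2 difference of 2.57 (camera adjusted p = 7.18e-16, 0.0693 with an estimated correlation, median 1.61 without KO day 15 replicate 4). Clec4e, a receptor for microbial glycolipids on myeloid cells, rose by 4.65 ± 0.69. Among 28 IL-17-induced genes the median log2 difference was 1.31, and 6 rose (14 rose and 1 fell over the list alone, camera adjusted p = 1.28e-11, 0.0693 with an estimated correlation, median 0.68 without KO day 15 replicate 4). S100a8, S100a9, Saa3 and Cxcl2 belong to this list. The inflammatory cytokine genes had a median log2 difference of 1.49 over 15 members, of which 7 rose (10 over the list alone, camera adjusted p = 1.28e-11, 0.0693 with an estimated correlation). The chemokines Ccl4 (3.98 ± 0.69) and Ccl3 (3.72 ± 0.67) and Il1a (2.35 ± 0.44) were among them. At day 15, 83 genes rose and 55 fell in KO, and the share of rises of 60.1% was 75.7% without quantile normalization. KO day 15 replicate 4 was highest for the neutrophil and cytokine lists, and its gap to the next array was 0.949 and 0.905 of the range of the group. The count of 138 was 59 without KO untreated replicate 1, 69 without KO untreated replicate 2, 71 without KO untreated replicate 4, 78 without KO day 15 replicate 1, 630 without KO day 15 replicate 2, 461 without KO day 15 replicate 3 and 39 without KO day 15 replicate 4, and 58 without replicate 4 of both genotypes.

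KO tumors, compared with untreated KO colon, had Mmp7 higher by 8.16 ± 0.41, Itln1 by 7.18 ± 0.46, S100a8 and S100a9 by 6.89 ± 1.21 and 6.35 ± 1.15, Reg3b by 6.75 ± 0.91, Pnliprp1 by 6.59 ± 0.49, the metallothionein Mt4 by 5.98 ± 0.88 and Saa3 by 5.92 ± 0.81. The bile acid-binding protein Fabp6 (-5.22 ± 0.51), Slc37a2 (-4.67 ± 0.44), S100g (-4.02 ± 0.56), the water channel Aqp8 (-4.00 ± 0.88), Dbp (-3.99 ± 0.36) and Slc26a3 (-3.92 ± 0.67) fell. These 14 genes had adjusted p = 0.00112 or lower. Among 20 Wnt/beta-catenin targets the median log2 difference was 2.72, and 16 rose (18 over the list alone, camera adjusted p = 2.4e-21, 0.0333 with an estimated correlation). Wif1, Prox1 and the Wnt deacylase Notum rose (5.80 ± 0.43, 4.18 ± 0.37 and 4.16 ± 0.39). Of the 13 intestinal stem cell genes, 9 rose (9 rose and 1 fell over the list alone), with a median log2 difference of 1.44 (camera adjusted p = 1.71e-06, 0.0649 with an estimated correlation). Lgr5 rose by 3.38 ± 0.40. The genes of interferon-gamma and antigen presentation had a median log2 difference of -1.85 over 17 members, of which 15 fell (16 over the list alone, camera adjusted p = 6.06e-14, 0.141 with an estimated correlation). Ciita, H2-DMb1 and Psmb9 fell (-1.78 ± 0.26, -2.54 ± 0.39 and -2.24 ± 0.38), from levels that in untreated KO were above untreated WT. Of the 12 genes of regenerative and fetal-type epithelium, 8 rose (8 over the list alone), with a median log2 difference of 1.20 (camera adjusted p = 7.81e-06, 0.147 with an estimated correlation). The tight junction gene Cldn4 (2.38 ± 0.29) and the secreted chaperone Clu (2.45 ± 0.52) rose.

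Of the 16 matrix metalloproteinases and their inhibitors, 10 rose (11 over the list alone), with a median log2 difference of 1.75 (camera adjusted p = 1.13e-08, 0.147 with an estimated correlation). Mmp10 and Mmp13 rose (5.22 ± 0.73 and 4.22 ± 0.66). Among 11 mast cell markers the median log2 difference was 1.02, and 6 rose (7 over the list alone, camera adjusted p = 1.01e-06, 0.0777 with an estimated correlation). Mcpt2 and Mcpt1 rose (5.14 ± 0.36 and 3.85 ± 0.47). The smooth muscle genes had a median log2 difference of -1.49 over 14 members, of which 11 fell (13 over the list alone, camera adjusted p = 1.59e-07, 0.292 with an estimated correlation). Myh11 and Pcp4 fell (-2.06 ± 0.43 and -2.84 ± 0.54). Of the 22 absorptive colonocyte genes, 2 rose and 12 fell (3 rose and 13 fell over the list alone), with a median log2 difference of -1.04 (camera adjusted p = 8.01e-07, 0.292 with an estimated correlation). Among 28 IL-17-induced genes the median log2 difference was 0.92, and 13 rose and 4 fell (14 rose and 4 fell over the list alone, camera adjusted p = 7.41e-05, 0.292 with an estimated correlation). Il23a rose by 1.09 ± 0.18 (adjusted p = 5.27e-05). In all, 1850 genes rose and 1695 fell between untreated KO colon and KO tumors.

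KO was also compared with WT at each later stage. In arrays labelled KO day 7, besides Il17rc, the nitric oxide regulator Ddah1 (-2.35 ± 0.42) and the branched-chain aminotransferase Bcat2 (-1.39 ± 0.24) were lower than in WT day 7. Sertad4 (1.37 ± 0.22), Mcm4 (1.24 ± 0.24) and the replication licensing factor Cdt1 (0.92 ± 0.16) were higher, and these 5 genes had adjusted p = 0.0112 or lower. The adjusted p of Ddah1 was 0.0682 without WT day 7 replicate 3, and that of Mcm4 was 0.0559 to 0.0734 without any 1 of WT day 7 replicate 2 and KO day 7 replicate 4. Of the 16 monocyte and macrophage markers, none passed over all genes (6 were lower over the list alone), with a median log2 difference of -0.73 (camera adjusted p = 3.31e-06, 0.798 with an estimated correlation, median -0.45 without WT day 7 replicate 3). The proliferation genes had a median log2 difference of 0.18 over 20 members, of which 1 was higher (3 over the list alone, camera adjusted p = 0.00186, 0.831 with an estimated correlation). At day 7, 14 genes were higher and 35 lower in arrays labelled KO, and 25 and 49 without quantile normalization. The count of 49 was 528 without WT day 7 replicate 1, 20 without any 1 of WT day 7 replicates 2 and 4, 13 without WT day 7 replicate 3, 158 without KO day 7 replicate 1, 19 without KO day 7 replicate 2, 18 without KO day 7 replicate 3 and 15 without KO day 7 replicate 4. It was 73 without the 2 arrays with high Il17rc and 416 without the 7 arrays with Krt5 above 100. With only the 2 groups compared in the fit, limma called 0 genes (2127 with an unadjusted p under 0.05), and Il17rc had adjusted p = 0.223.

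At day 15, the chemokine Ccl4 (3.22 ± 0.69), the interferon-stimulated genes Ifit2 (2.75 ± 0.58) and Cmpk2 (1.90 ± 0.39) and Gzma (1.78 ± 0.31) were higher in KO than in WT. Erdr1 (-3.28 ± 0.56), the neutrophil surface protein Cd177 (-1.87 ± 0.38) and Bcat2 (-1.06 ± 0.24) were lower, and these 7 genes had adjusted p = 0.0467 or lower. Among 14 type I interferon-stimulated genes the median log2 difference was 1.46, and 2 were higher (12 over the list alone, camera adjusted p = 9.97e-17, 0.0617 with an estimated correlation). Of the 20 proliferation genes, none passed over all genes (18 were higher over the list alone), with a median log2 difference of 0.93 (camera adjusted p = 2.41e-22, 0.0617 with an estimated correlation, median 0.59 without WT day 15 replicate 1). The inflammatory cytokine genes had a median log2 difference of 1.01 over 15 members, of which 2 were higher (8 were higher and 1 was lower over the list alone, camera adjusted p = 2.65e-07, 0.137 with an estimated correlation, median 0.45 without KO day 15 replicate 4). Most of these gene calls depended on single arrays. The adjusted p of Bcat2 was 0.0675 to 0.185 without any 1 of WT day 15 replicates 1, 2 and 3 and KO day 15 replicates 1, 2 and 4. For Ccl4 it was 0.0589 to 0.133 without any 1 of WT day 15 replicates 1, 2 and 3 and KO day 15 replicates 2 and 4, for Cd177 0.0667 to 0.116 without any 1 of WT day 15 replicates 1, 2 and 3 and KO day 15 replicates 1 and 2, for Cmpk2 0.0541 to 0.116 without any 1 of WT day 15 replicates 1 and 3 and KO day 15 replicates 1 and 2, for Gzma 0.0557 without KO day 15 replicate 2 and for Ifit2 0.0532 to 0.118 without any 1 of WT day 15 replicates 1, 3 and 4 and KO day 15 replicates 1, 2 and 4. At day 15, 29 genes were higher and 9 lower in KO, a share of 76.3% higher that was 91.8% with each array centred on its median and 90.7% without quantile normalization. The count of 38 was 5 without WT day 15 replicate 1, 14 without WT day 15 replicate 3, 118 without WT day 15 replicate 4, 15 without KO day 15 replicate 1, 11 without KO day 15 replicate 2 and 116 without KO day 15 replicate 3, and 28 with the replicate numbers as a block.

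Between KO and WT tumors, 9 genes differed. Besides Il17rc, the cell adhesion genes Ceacam10 (-1.95 ± 0.37) and Ceacam12 (-1.86 ± 0.23), Cd177 (-1.72 ± 0.31), Bcat2 (-1.19 ± 0.19) and the netrin Ntn5 (-0.65 ± 0.11) were lower in KO tumors. The ribonuclease P subunit Pop4 (1.07 ± 0.20) and the dopamine receptor Drd4 (0.41 ± 0.08) were higher, and Clca3b, the remaining call, had overlapping arrays. The named genes had adjusted p = 0.0313 or lower, and 423 genes had an unadjusted p under 0.05. Of the 9 genes, 7 lie on chromosome 7, which holds 1305 of the 16923 genes with a known chromosome (Fisher's exact test, two-sided, adjusted p = 1e-05), while Il17rc lies on chromosome 6. Of the 14 type I interferon-stimulated genes, none passed over all genes (none over the list alone), with a median log2 difference of 0.46 (camera adjusted p = 3.66e-05, 0.968 with an estimated correlation, median 0.29 without WT tumor replicate 3, median 0.12 without KO tumor replicate 1, median 0.73 without KO tumor replicate 6). This list passed no longer without KO tumor replicate 1 (camera adjusted p = 0.379). The adjusted p of Cd177 was 0.0572 to 0.066 without any 1 of WT tumor replicate 1 and KO tumor replicate 4, that of Ceacam10 0.0515 to 0.104 without any 1 of WT tumor replicates 1, 2, 3 and 5 and KO tumor replicates 1, 2, 3 and 4, that of Drd4 0.0515 to 0.123 without any 1 of WT tumor replicates 1, 2, 3, 4, 5 and 6 and KO tumor replicates 1, 2, 5 and 6 and that of Pop4 0.0676 to 0.0914 without any 1 of WT tumor replicates 1, 4 and 5 and KO tumor replicates 2 and 4. The count was 4 without WT tumor replicate 1, 5 without any 1 of WT tumor replicate 5 and KO tumor replicates 2 and 4 and 17 without WT tumor replicate 6.

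**Figure D3:**
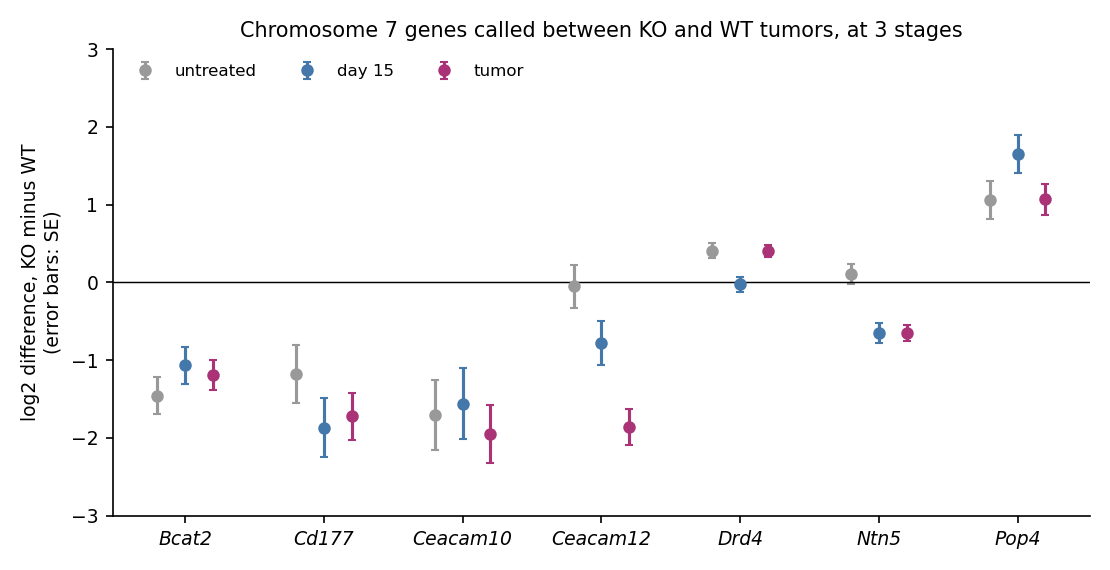
Log2 difference of KO minus WT (± SE of the limma model) for 7 genes on chromosome 7 at 3 stages, untreated, day 15 and tumor, with day 7 left out because of the doubt about a label. Bcat2, Cd177 and Ceacam10 lie below 0 and Pop4 above 0 at all 3 stages.

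Whether KO and WT responded differently was tested with interactions, the change from untreated in KO minus that in WT. At day 7 the responses of interferon-stimulated genes differed, with Ido1 at -7.36 ± 1.11, Tgtp1 at -7.18 ± 0.95, Ubd at -7.12 ± 0.88, Ifi47 at -6.16 ± 0.71 and Iigp1 at -6.15 ± 0.93, and so did that of Retnlb (-6.22 ± 1.05). Sertad4 went the other way (2.44 ± 0.31). These 7 genes had adjusted p = 0.000451 or lower. Of the 17 genes of interferon-gamma and antigen presentation, 16 were negative (17 over the list alone), with a median log2 difference of -3.85 (camera adjusted p = 1.08e-34, 0.0173 with an estimated correlation). Psmb8 and Cd74 were among them (-3.56 ± 0.50 and -4.59 ± 0.66). The type I interferon-stimulated genes had a median log2 difference of -2.76 over 14 members, of which 8 were negative (13 over the list alone, camera adjusted p = 1.87e-15, 0.0816 with an estimated correlation). Among 16 T cell markers the median log2 difference was -0.86, and 4 were negative (10 over the list alone, camera adjusted p = 3.4e-10, 0.0637 with an estimated correlation). Gzma and Gzmb had -3.56 ± 0.44 and -3.02 ± 0.47. Of the 8 plasma cell markers, 3 were negative (7 over the list alone), with a median log2 difference of -1.52 (camera adjusted p = 3.15e-07, 0.0443 with an estimated correlation). Jchain and Ccl7 had -4.74 ± 0.81 and -2.78 ± 0.60. The untreated difference between the genotypes enters every interaction. In all, 404 genes had an interaction at day 7, 109 positive and 295 negative, and 72 were positive and 274 negative with each array centred on its median. The count was 256 without WT untreated replicate 4, 898 without WT day 7 replicate 1 and 206 without WT day 7 replicate 3, and 290 without the 2 arrays with high Il17rc.

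At day 15 the interaction was negative for the interferon-inducible GTPases Gbp2b (-2.47 ± 0.25) and Ifi47 (-3.50 ± 0.71) and for Il18bp (-2.75 ± 0.52), and positive for Plekha1 (0.82 ± 0.17), with adjusted p = 0.0454 or lower. Among 17 genes of interferon-gamma and antigen presentation the median log2 difference was -2.37, and none passed over all genes (16 were negative over the list alone, camera adjusted p = 1.14e-24, 0.0885 with an estimated correlation). The neutrophil markers had a median log2 difference of 1.58 over 17 members, of which none passed over all genes (none over the list alone, camera adjusted p = 6.57e-05, 0.741 with an estimated correlation, median 2.57 without WT day 15 replicate 4, median 0.57 without KO day 15 replicate 4). The neutrophil list passed no longer without KO day 15 replicate 4 (camera adjusted p = 0.0587). The adjusted p of Ifi47 was 0.0591 to 0.147 without any 1 of WT untreated replicates 2, 3 and 4, WT day 15 replicates 1 and 2, KO untreated replicates 2, 3 and 4 and KO day 15 replicates 1, 2, 3 and 4, that of Il18bp 0.0512 to 0.102 without any 1 of WT untreated replicates 3 and 4, WT day 15 replicates 1 and 2, KO untreated replicates 2, 3 and 4 and KO day 15 replicates 2, 3 and 4 and that of Plekha1 0.0532 to 0.183 without any 1 of WT untreated replicates 2, 3 and 4, WT day 15 replicates 1, 2 and 3, KO untreated replicates 1, 2, 3 and 4 and KO day 15 replicates 1, 3 and 4. The count of 14 genes, 1 positive and 13 negative, was 24 without WT untreated replicate 1, 1 without any 1 of WT untreated replicates 3 and 4, WT day 15 replicates 1 and 2, KO untreated replicates 3 and 4 and KO day 15 replicates 3 and 4, 95 without WT day 15 replicate 4, 2 without KO untreated replicate 2 and 5 without any 1 of KO day 15 replicates 1 and 2.

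In tumors the interaction was negative for Ido1 (-6.58 ± 1.01), Ubd (-6.32 ± 0.80), Tgtp1 (-5.33 ± 0.86), Cxcl9 (-5.02 ± 1.14), Ifi47 (-4.37 ± 0.65), Retnlb (-4.34 ± 0.96) and the class II loading factor H2-DMa (-4.11 ± 0.69). It was positive for Itih2 (1.82 ± 0.36) and Dpyd (1.52 ± 0.28), and these 9 genes had adjusted p = 0.0187 or lower. Of the 17 genes of interferon-gamma and antigen presentation, 15 were negative (17 over the list alone), with a median log2 difference of -3.16 (camera adjusted p = 6.52e-44, 0.00451 with an estimated correlation). The type I interferon-stimulated genes had a median log2 difference of -2.02 over 14 members, of which 4 were negative (11 over the list alone, camera adjusted p = 6.59e-16, 0.0985 with an estimated correlation). Among 16 T cell markers the median log2 difference was -0.47, and 2 were negative (6 over the list alone, camera adjusted p = 9.85e-08, 0.128 with an estimated correlation). Gzma had -2.80 ± 0.40. In all, 134 genes passed, 12 positive and 122 negative, and 83 passed without the 7 arrays with Krt5 above 100.

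Stages were then compared over the mean of both genotypes. From day 7 to day 15, Saa3 rose by 6.06 ± 0.63, Cxcl13 by 4.53 ± 0.65, Il1b by 4.43 ± 0.60, S100a8 by 4.31 ± 0.94, the B cell surface protein Ms4a1 by 4.27 ± 0.69, Retnlb by 4.24 ± 0.52, Trim15 by 4.23 ± 0.33 and Lrg1 by 4.10 ± 0.36, while Cyp2c55 (-3.32 ± 0.64) and Pcp4 (-3.06 ± 0.42) fell. These 10 genes had adjusted p = 0.000813 or lower. Of the 20 proliferation genes, 19 rose (19 over the list alone), with a median log2 difference of 1.19 (camera adjusted p = 1.98e-21, 0.0718 with an estimated correlation). Mcm4 and Top2a rose by 1.89 ± 0.17 and 1.97 ± 0.20. Among 16 monocyte and macrophage markers the median log2 difference was 1.996, and 16 rose (16 over the list alone, camera adjusted p = 1.22e-16, 0.0718 with an estimated correlation). Lyz2 and the complement component C1qb rose (2.15 ± 0.21 and 2.95 ± 0.37). The B cell markers had a median log2 difference of 1.70 over 11 members, of which 10 rose (10 over the list alone, camera adjusted p = 1.91e-09, 0.137 with an estimated correlation). Of the 17 neutrophil markers, 12 rose (13 over the list alone), with a median log2 difference of 2.06 (camera adjusted p = 3.56e-07, 0.212 with an estimated correlation). Among 28 IL-17-induced genes the median log2 difference was 1.02, and 18 rose (19 rose and 1 fell over the list alone, camera adjusted p = 6.9e-10, 0.0823 with an estimated correlation). The smooth muscle genes had a median log2 difference of -1.11 over 14 members, of which 12 fell (13 over the list alone, camera adjusted p = 6.18e-07, 0.233 with an estimated correlation). Of the 13 squamous epithelium markers, 6 fell (7 over the list alone), with a median log2 difference of -2.37 (camera adjusted p = 0.00691, 0.503 with an estimated correlation). Of the day 7 arrays, 4 had Krt5 above 100 and of the day 15 arrays none had. In all, 2283 genes rose and 2521 fell, a share of rises of 47.5% that was 63.7% with each array centred on its median and 63.7% without quantile normalization.

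From day 15 to tumors, Itln1 rose by 7.13 ± 0.32, Pnliprp1 by 6.51 ± 0.35, Mmp7 by 5.66 ± 0.29, Defa21 by 5.63 ± 0.56 and Wif1 by 5.32 ± 0.30, while Slc26a3 (-3.37 ± 0.47), Fabp6 (-2.78 ± 0.36) and Aqp8 (-2.73 ± 0.62) fell, with adjusted p = 0.000938 or lower. Among 20 Wnt/beta-catenin targets the median log2 difference was 3.26, and 18 rose (19 over the list alone, camera adjusted p = 8.09e-26, 0.0124 with an estimated correlation). The intestinal stem cell genes had a median log2 difference of 1.71 over 13 members, of which 9 rose (9 over the list alone, camera adjusted p = 4.43e-08, 0.0173 with an estimated correlation). Lgr5, Ascl2 and Axin2 rose by 4.18 ± 0.28, 3.36 ± 0.27 and 3.33 ± 0.28. Of the 20 proliferation genes, 17 rose (17 over the list alone), with a median log2 difference of 0.82 (camera adjusted p = 4.43e-08, 0.538 with an estimated correlation). Among 12 enteroendocrine cell genes the median log2 difference was -0.95, and 10 fell (10 over the list alone, camera adjusted p = 5.91e-08, 0.22 with an estimated correlation). The hormone genes Insl5 (-2.84 ± 0.48), Pyy (-2.13 ± 0.22) and Sct (-1.66 ± 0.20) fell. The absorptive colonocyte genes had a median log2 difference of -0.78 over 22 members, of which 2 rose and 14 fell (3 rose and 15 fell over the list alone, camera adjusted p = 3.19e-06, 0.538 with an estimated correlation). Of the 11 mast cell markers, 7 rose (8 over the list alone), with a median log2 difference of 0.56 (camera adjusted p = 7.12e-05, 0.22 with an estimated correlation). Mcpt2 rose by 3.70 ± 0.26 and Il23a by 0.98 ± 0.13. In all, 3069 genes rose and 2371 fell, a share of rises of 56.4% that was 48.8% without quantile normalization, with 2661 rises and 2792 falls.

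The likeness of both responses was measured across genes, which are not independent replicates, so no p is given. WT and KO responses share no array. The log2 changes from untreated in WT and KO had Pearson's r of 0.108 (Spearman's rho 0.132) at day 7, 0.557 (0.394) at day 15 and 0.735 (0.656) in tumors, as 3 correlations in this family. At day 7, r was -0.0540 without WT day 7 replicate 1, 0.0242 without WT untreated replicate 2, 0.245 without WT day 7 replicate 3 and 0.185 without KO day 7 replicate 1, and 0.00703 without the 7 arrays with Krt5 above 100. At day 15 it was 0.342 without WT day 15 replicate 4. In tumors, 1203 genes rose and 1011 fell in both genotypes, where independent lists of these sizes would share 232 and 172, and 40 went opposite ways. At day 7 the shared counts were 10 and 174 (independent lists, 2.93 and 15.1), and at day 15 they were 23 and 15 (1.74 and 0.705). Of 224 camera calls over 525 combinations of list and comparison, 17 also passed with an estimated correlation. These were proliferation genes (day 7, both genotypes), antimicrobial genes (WT day 15, WT tumors), Wnt targets (tumors of both genotypes against untreated, and tumors against day 15) and stem cell genes (tumors against day 15). They further were the interferon-gamma list (untreated KO against WT, KO day 7, and the interactions at day 7 and in tumors), the type I interferon and T cell lists (untreated KO against WT) and plasma cell markers (untreated KO against WT, KO day 7 and the day 7 interaction). Median, mean and test had the same sign for every camera call.

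**Figure D4:**
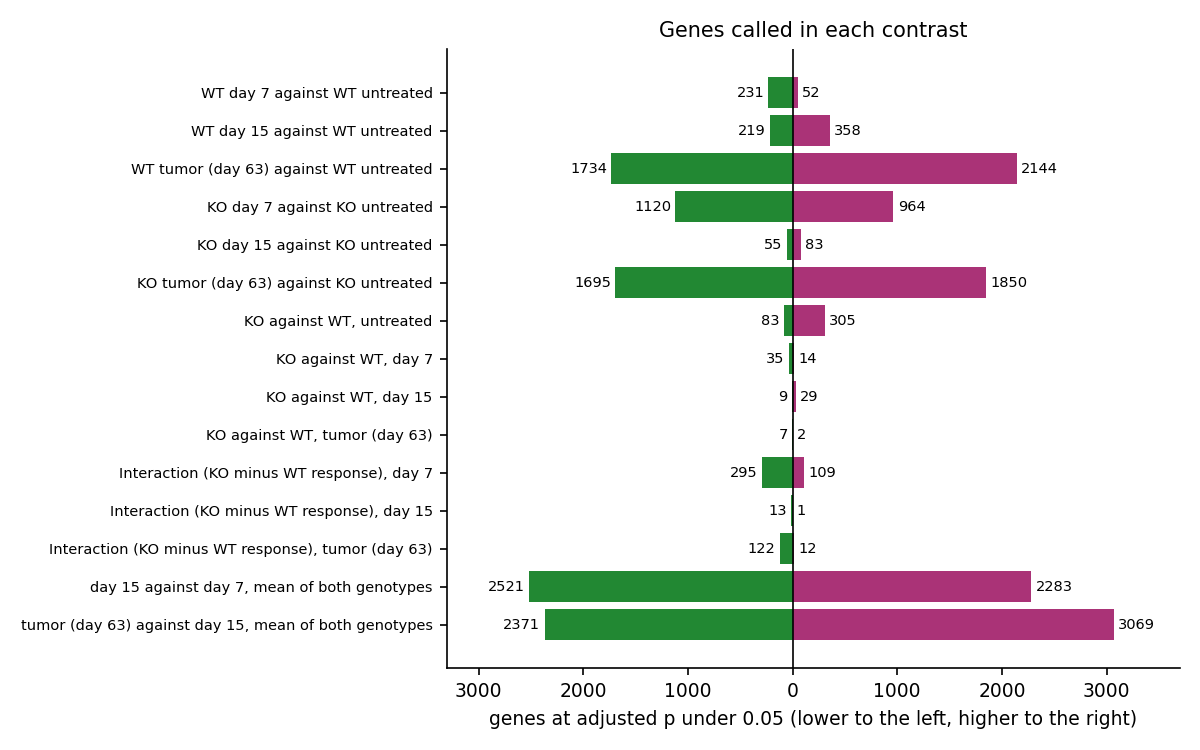
Number of genes past an adjusted p of 0.05 in each of the 15 comparisons, with genes higher drawn to the right of 0 and genes lower to the left. Counts range from 9 between KO and WT tumors to 5440 between tumors and day 15.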

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

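All tests of explanations in this part were chosen only after the results were seen. A gap ratio, the distance from the highest or lowest array of a group to the next divided by the range of the group, was computed 569 times, for 117 genes and 22 lists. Of these, 52 passed Dixon's 95% critical value, and chance flags about 1 in 20 groups, which would give 28.4.

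The array labelled KO day 7 replicate 1 had an Il17rc level inside the WT range, and replicate 2 had a level between the genotypes. The 8 genes used were picked to separate the genotypes at other stages and in the day 7 arrays that set the scale. Over them the median position of replicate 2 was 0.122, where 0 is the mean of the other KO day 7 arrays and 1 that of WT day 7. This argues against a WT animal in replicate 2. An exchange of a WT and a KO array is argued against, with Il17rc at 76 or more in arrays labelled WT and at most 15 in low KO arrays. Replicate 1 had a median position of 0.8 (range 0.234 to 1.48), with 0.779 over the 5 linked genes on chromosome 7 and 1.15 over the others. A wild-type animal with a KO label is thus a candidate explanation. However, Bcat2, Ceacam10 and Creld1 lay below the lowest WT day 7 array, which is itself in the WT mean. Creld1, like Il17rc on chromosome 6, was at 0.234 against 0.831. A sample mixed from WT and KO tissue stays open, with linear positions of 0.795 for Il17rc and 0.0789 to 1.28 for the genes, and WT RNA in replicate 2 cannot be told apart from none, because its median linear position of 0.0648 was -0.0173 from the 0.082 that Il17rc needs and the spread of the genes was 0.0972. The design gives no biological explanation for a difference within a group, and none was tested.

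Interferon and antigen-presentation genes were higher in untreated KO than in untreated WT. Squamous tissue in untreated WT samples is argued against, since the median log2 difference of the list was 3.11 without the arrays with squamous markers, with 15 of 17 members higher. A constant difference between the genotypes is argued against as well, since the median between KO and WT tumors was 0.0278. All 4 untreated KO arrays, the lowest with a list mean of 9.46, lay above all untreated WT arrays, the highest with 7.01, so a difference in housing, litter or infection cannot be told apart from genotype, because the labels used here give neither cage nor litter. An effect of the genotype that varies by stage stays open as a biological hypothesis and was not tested, and at day 15 all KO arrays lay above all WT arrays for the type I interferon list (lowest 7.38, highest 6.27), while the interferon-gamma list averaged 8.76 in KO and 7.9 in WT with overlapping arrays.

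Of the 9 genes called between KO and WT tumors, 7 lie on chromosome 7. Random placement is argued against by the adjusted Fisher's exact p of 1e-05. A difference fixed in the DNA of the animals, such as flanking or strain sequence, may contribute but cannot be told apart from a change in expression, with 11 of 14 tests of these genes in untreated and day 15 arrays in the direction of the tumors at an unadjusted p under 0.05. A sequence variant under the probes stays open too, since a second probe set of Ceacam10 differed alike by a log2 value of -2.02 and 1 of 2 genes with another probe set passed, while that of Drd4 was dim, with a difference of 0.01. Clustering of all 7 genes by median distance was not detected (permutation p = 0.102), leaving a block of some open. A genotype effect on these genes stays open, untested.

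Arrays that stood apart from their group by the gap ratio are given with that ratio. WT tumor replicate 6 was lowest for Defa21 (0.699), Lgr5 (0.684), Mmp7 (0.666), Prox1 (0.736), Sp5 (0.767), Wif1 (0.875), the Wnt target list (0.763) and the stem cell list (0.666) and highest for Myh11 (0.719), Slc37a2 (0.772), Synm (0.701), Il17rc (0.668), Pyy (0.741) and the smooth muscle list (0.912). KO day 15 replicate 4 was lowest for Slc26a3 (0.928) and highest for Ccl3 (0.85), Ccl4 (0.842), Clec4e (0.857), S100a8 (0.86), Saa3 (0.863), the neutrophil list (0.949) and the cytokine list (0.905). KO untreated replicate 3 was lowest for Itln1 (0.988) and Mmp13 (0.831) and highest for Notum (0.971) and Prox1 (0.972). WT day 15 replicate 1 was lowest for Top2a (0.989) and the proliferation list (0.852) and highest for Itln1 (0.877) and Pnliprp1 (0.904). WT day 15 replicate 4 was lowest for Ido1 (0.849) and the type I interferon list (0.878) and highest for Ccl4 (0.846). WT untreated replicate 1 was highest for Wif1 (0.883), Il18bp (0.855) and the type I interferon list (0.949). WT day 15 replicate 3 was lowest for Ccl8 (0.855) and Il23a (0.846). KO untreated replicate 2 was lowest for Mmp7 (0.992) and highest for Ccl7 (0.851). KO day 7 replicate 1 was highest for Cdk1 (0.834) and Bcat2 (0.873). KO tumor replicate 1 was highest for Fabp6 (0.694) and Pcp4 (0.635). KO untreated replicate 1 was lowest for the interferon-gamma list (0.855) and highest for Il23a (1). KO day 15 replicate 3 was lowest for Mcm4 (0.858) and highest for Defa21 (0.878). WT day 15 replicate 2 was lowest for Mcpt2 (0.863) and highest for the squamous list (0.892). WT untreated replicate 4 was lowest for Ascl2 (0.846). KO tumor replicate 2 was lowest for Insl5 (0.63). Of the 42 ratios of genes, 11 come from groups with a mean intensity below 16, with at most 13 units from lowest to highest. These 11 do not show an array apart on their own. They are those of Wif1 and Il18bp in WT untreated, Il23a, Itln1, Mmp7, Notum and Prox1 in KO untreated, Bcat2 in KO day 7, Defa21 in KO day 15 and Il23a and Itln1 in WT day 15.

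Effects that differed between the genotypes by the interaction test, or for lists by camera, are given in log2 units, with the camera adjusted p at an estimated correlation beside each list. Lists with 0.05 or more there lost their call. At day 7, 404 genes passed, and the values were the interferon-gamma list (-3.85, 0.0173), the type I interferon list (-2.76, 0.0816), the T cell list (-0.864, 0.0637), the plasma cell list (-1.52, 0.0443), Ccl7 (-2.78), Cd74 (-4.59), Gzma (-3.56), Gzmb (-3.02), Ido1 (-7.36), Ifi47 (-6.16), Iigp1 (-6.15), Jchain (-4.74), Psmb8 (-3.56), Retnlb (-6.22), Sertad4 (2.44), Tgtp1 (-7.18) and Ubd (-7.12). At day 15, 14 genes passed, and the values were the interferon-gamma list (-2.37, 0.0885), the neutrophil list (1.58, 0.741), Gbp2b (-2.47), Ifi47 (-3.5), Il18bp (-2.75) and Plekha1 (0.824). No neutrophil member passed, and that list lost its call without KO day 15 replicate 4 (camera adjusted p = 0.0587). In tumors, 134 genes passed, and the values were the interferon-gamma list (-3.16, 0.00451), the type I interferon list (-2.02, 0.0985), the T cell list (-0.473, 0.128), Cxcl9 (-5.02), Dpyd (1.52), Gzma (-2.8), H2-DMa (-4.11), Ido1 (-6.58), Ifi47 (-4.37), Itih2 (1.82), Retnlb (-4.34), Tgtp1 (-5.33) and Ubd (-6.32).

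Other splits of the same arrays were counted, given as the real count, the splits with as many genes including the real one, and the highest other. A share under 0.05 was taken to argue against chance, without adjustment over the 15 comparisons. This was so for WT day 15 (577, 1 of 35, 116) and WT tumors (3878, 1 of 100, 2540) against untreated. It was also so for KO day 7 (2084, 1 of 35, 46) and KO tumors (3545, 1 of 100, 1648) against untreated and KO against WT untreated (388, 1 of 35, 4). The same held for day 15 against day 7 (4804, 1 of 100, 1686) and tumors against day 15 (5440, 1 of 100, 1831). For the tumor interaction (134, 2 of 100, 204), another split called more genes, so chance stays possible. Chance cannot be excluded for KO day 15 against untreated (138, 2 of 35, 191) and KO against WT at day 7 (49, 2 of 35, 557) and in tumors (9, 7 of 100, 113). The day 15 interaction (14, 12 of 100, 2460) is undecided too, since its splits exchanged untreated arrays as well and ignore the day 15 pairs. Splits that call several times the real count point to a structure of the samples. At day 7, the highest split of KO and WT exchanged both replicate 1 arrays, and at day 15 it set replicates 1 and 4 of both genotypes against 2 and 3. In tumors it exchanged WT replicate 6 and KO replicate 2. Equal replicate numbers had correlated residuals for WT day 7 against untreated (283, 1 of 35, 164) and KO against WT at day 15 (38, 6 of 35, 3427). The first leaves pairing open, as 1 array matched its own number best and replicates 1 and 4 held squamous tissue. If paired, the 7 other splits parting every pair (at most 4 and 1 genes) are too few for a share under 0.05.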

How the results depend on the processing

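Chosen only after the results were seen were the tests without quantile normalization, without the arrays with squamous markers, high Il17rc, Y-linked transcripts or the day 15 replicates 4, and with the squamous level as a covariate. Of 226 values of named genes, 180 kept their direction and side of the threshold in every alternative that gave a value for them and without each array of the groups compared, and so did 17 of 224 list calls. The named genes were chosen in part for keeping their call without single arrays, so this share says little about other genes. Robust moderation and moderation without trend changed no count by over 1.5 times. Signals near background limit what the dimmest genes can show. Camera with an estimated correlation called 17 lists of all contrasts and fry called 133. Calls of KO against WT on the chromosome of Il17rc had odds ratios of 1.34 untreated, 1.93 at day 7, 0.458 at day 15 and 2.12 in tumors (Fisher's exact p = 0.144, 0.195, 0.723 and 0.403). At an unadjusted p under 0.01 they were 1.35, 1.18, 1.22 and 2.16 (Fisher's exact p = 0.0309, 0.281, 0.237 and 0.0433, and 0.139, 0.715, 0.658 and 0.433 adjusted over chromosomes). Where the number of features or samples does not show it, the cause was not tested.

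With every probe set tested, which tests more features, the counts were 452 for WT day 7 against untreated, 6796 for WT tumors against untreated, 3919 for KO day 7 against untreated, 5821 for KO tumors against untreated, 602 for KO against WT untreated, 136 for KO against WT at day 7, 23 for the day 15 interaction, 10065 for day 15 against day 7 and 10499 for tumors against day 15. With array weights the counts were 1447 for WT day 7 against untreated, 942 for WT day 15 against untreated, 4851 for KO day 7 against untreated, 217 for KO day 15 against untreated, 5695 for KO tumors against untreated, 894 for KO against WT untreated, 3493 for KO against WT at day 7, 21 for KO against WT in tumors, 2504 for the day 7 interaction, 97 for the day 15 interaction and 337 for the tumor interaction, the sign of the squamous list in the day 7 interaction turned at camera adjusted p = 0.777, r day 7 was 0.184 and r tumors was 0.772. With only the groups compared in the fit, which leaves fewer arrays, the counts were 153 for WT day 7 against untreated, 145 for WT day 15 against untreated, 3188 for KO day 7 against untreated, 38 for KO day 15 against untreated, 0 by limma for KO against WT at day 7 (2127 with an unadjusted p under 0.05), 2 for KO against WT at day 15 and 4 for KO against WT in tumors, the log2 value of Il17rc in KO day 7 against untreated was 1.83 and Il17rc in KO against WT at day 7 was -3.41 and passed no longer. With the number of the title code as a block the counts were 162 for WT day 7 against untreated, 297 for WT day 15 against untreated, 89 for KO day 15 against untreated, 27 for KO against WT at day 7, 13 for KO against WT at day 15 and 1 for the day 15 interaction. With its letter as a block the counts were 119 for WT day 7 against untreated, 47 for WT day 15 against untreated, 2395 for WT tumors against untreated, 1298 for KO day 7 against untreated, 44 for KO day 15 against untreated, 227 for KO against WT untreated, 27 for KO against WT at day 7, 8 for KO against WT at day 15, 5 for KO against WT in tumors and 2 for the day 15 interaction, the log2 value of Il17rc in KO day 7 against untreated was 1.74 and passed no longer, the sign of the goblet cell list in KO against WT in tumors turned at camera adjusted p = 0.977, r day 7 was 0.300, r day 15 was 0.463 and r tumors was 0.67. Without the 7 arrays with squamous markers (KO tumor replicate 1, with Krt5 at 96, stayed), thus with fewer samples, the counts were 66 for WT day 7 against untreated, 266 for WT day 15 against untreated, 256 for KO against WT untreated, 416 for KO against WT at day 7, 8 for the day 15 interaction and 83 for the tumor interaction, the log2 value of Il17rc in KO day 7 against untreated was 0.11 and passed no longer, the sign of the squamous list in WT day 15 against untreated turned at camera adjusted p = 0.232, squamous list in WT tumors against untreated turned at camera adjusted p = 0.102, squamous list in KO against WT untreated turned at camera adjusted p = 0.186, squamous list in the day 7 interaction turned at camera adjusted p = 0.454, squamous list in the day 15 interaction turned at camera adjusted p = 0.25 and squamous list in day 15 against day 7 turned at camera adjusted p = 0.5259, r day 7 was 0.00703, r day 15 was 0.666 and r tumors was 0.79. Without replicate 4 of both genotypes at day 15 the counts were 58 for KO day 15 against untreated and 56 for the day 15 interaction, the sign of the fibroblast list in tumors against day 15 turned at camera adjusted p = 0.971, r day 15 was 0.388. Without the dimmest genes the counts were 79 for KO against WT at day 7 and 23 for the day 15 interaction. With the mean of all probe sets of a gene the counts were 30 for KO against WT at day 7, the log2 value of Il17rc in KO day 7 against untreated was 0.91 and passed no longer. Without quantile normalization the counts were 74 for KO against WT at day 7, 108 for KO against WT at day 15 and 9 for the day 15 interaction. With the squamous level as a covariate the counts were 179 for KO against WT at day 7, the log2 value of Il17rc in KO day 7 against untreated was 1.58 and passed no longer, the sign of the squamous list in day 15 against day 7 turned at camera adjusted p = 0.913, r day 7 was 0.231, r day 15 was 0.661 and r tumors was 0.783. With each array centred on its median the counts were 98 for KO against WT at day 15 and 8 for the day 15 interaction. Without the array with Y-linked transcripts the counts were 5 for KO against WT in tumors. With a pseudocount of 16 the log2 value of Il17rc in KO day 7 against untreated was 1.28 and passed no longer. Without the 2 arrays labelled KO day 7 with high Il17rc the log2 value of Il17rc in KO day 7 against untreated was 0.11 and passed no longer, r day 7 was 0.216.

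With the replicate numbers as a block, as for a pairing, the counts were 27 for KO against WT at day 7 and 9 for the day 15 interaction.

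Leaving out each array in turn gave 188 to 268 for WT day 7 against untreated, 311 to 694 for WT day 15 against untreated, 1315 to 2276 for KO day 7 against untreated, 39 to 630 for KO day 15 against untreated, 13 to 528 for KO against WT at day 7, 5 to 118 for KO against WT at day 15, 4 to 17 for KO against WT in tumors, 206 to 898 for the day 7 interaction, 1 to 95 for the day 15 interaction, 0.78 to 2.45 for Il17rc in KO day 7 against untreated, 5.75e-05 to 0.766 for adjusted p of the pan-epithelial list in KO against WT at day 15, 5.44e-08 to 0.718 for adjusted p of the fibroblast list in KO against WT at day 15, -0.054 to 0.245 for r day 7, 0.342 to 0.624 for r day 15 and 0.676 to 0.776 for r tumors.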

Other observations

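No tests in this part were chosen after the results were seen, although the lists printed were. Among genes of type 17 cytokines and cells in WT tumors, 2 rose of 9 (2 rose over the list alone, median 0.48, camera adjusted p = 0.0409, 0.279 with an estimated correlation). Among type 17 genes from day 7 to day 15 over both genotypes, 3 rose of 9 (4 rose over the list alone, median 0.19, camera adjusted p = 0.00916, 0.137 with an estimated correlation). Among type 17 genes between untreated KO and WT, none passed of 9 (none over the list alone, median -0.03, camera adjusted p = 0.657, 0.887 with an estimated correlation). Among IL-17-induced genes between untreated KO and WT, 1 was higher of 28 (1 was higher over the list alone, median 0.10, camera adjusted p = 0.601, 0.887 with an estimated correlation). Among IL-17-induced genes between KO and WT tumors, none passed of 28 (2 were lower over the list alone, median 0.02, camera adjusted p = 0.481, 0.968 with an estimated correlation).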
